A study of Homo sapiens with 10 samples.

How the data were processed

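RNA of MOLT-4 cells, a human T-cell acute lymphoblastic leukaemia line, was measured on Affymetrix human expression arrays, which read each transcript with 1 or more probe sets of short oligonucleotides. The labels give 10 arrays, with 2 replicates at each of 5 times of treatment (0 h, 0.5 h, 1 h, 3 h, 6 h) with MABL, an antibody against CD47. Per the labels, every sample, those of 0 h included, carries 10 ug/mL MABL and 50 ug/mL of an agent abbreviated GAM, which the labels do not spell out. No array of untreated cells kept for the same time was analysed here, so a difference from 0 h holds the antibody, GAM, the time in culture and the handling together. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

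The deposited values are a score per probe set made with GCRMA, per the submitters' processing notes, which corrects for background by probe sequence, normalizes between arrays and combines the probes of a set. The version is not given in the sources used here, and neither are the scale or any step after GCRMA. The deposited scores ran from 1.25e-05 to 238.1, with array medians of 8.161 to 8.564, a range that suits neither plain log2 values nor linear intensities. Their square roots reached 15.43. The replicate SD of the square roots was not level over the whole range: it was 0.00313 for deposited scores up to 4, 0.0106 for those of 4 to 9, 0.0355 for 9 to 16 and 0.104 for 16 to 25. Above that it was 0.143 for scores of 25 to 36, 0.152 for 36 to 64 and 0.0910 for 144 to 250, while the SD of log2 of the scores went from 0.0752 for 25 to 36 to 0.0199 for 144 to 250. On the scores themselves the SD was 1.57 for 25 to 36, 2.12 for 36 to 64 and 2.44 for 144 to 250. The replicates therefore do not tell the square roots from the untransformed scores. Against log2 of the scores, the argument from the replicates covers scores of 25 and more, the level of the filter, and not those below. The dimmest probe set gave an SD of 0.00702 on the square roots, where the median of probe sets under 3 was 0.00796, against 1.75 and 0.0141 on log2 of the scores and 0.000204 and 0.0266 on the scores themselves. From the range and this probe set, the square root was read as log2 expression and used throughout. This scale is a reading of the data and not stated by the authors, and all sizes given as log2 changes or folds depend on it.

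The table held 22283 probe sets, of which 68 Affymetrix control probe sets were left out of the tests and kept as measures of the arrays. Probe sets with at least 2 of the 10 arrays at log2 5 or higher, a deposited score of 25, were tested. This filter ignores the groups and kept 4276, or 19.2% of the 22215 others. Gene names came from the platform annotation, updated through gene identifiers to the symbols of the RefSeq table of GRCh38.p14, from which no coordinate is printed because no genome build was named for the files. Of all probe sets, 19071 had 1 symbol (19059 matched a current one), 1043 had several and 2169 had none. Genes were named only from probe sets with 1 symbol, and the tested probe sets of this kind stood for 2819 genes.

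Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 10 arrays with time as the only factor, so that the 5 times shared 1 estimate of the spread with 5 residual degrees of freedom (prior degrees of freedom 3.06, prior SD 0.139). Each later time was compared with 0 h, successive times with each other, and all times together with an F test. A probe set was called at an adjusted p (Benjamini-Hochberg within the comparison) under 0.05, and every adjusted p of a gene is limma's. The submitters' fold rule was computed beside it: both replicates above 2 or below 0.5 times the geometric mean of the 0 h arrays. Errors are SEs from the fit or SDs over n = 2 arrays.

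Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with 1 probe set per gene (the brightest on average). Of 28 lists holding 727 genes, 27 had measured members, which gave 108 tests over 4 times, adjusted together. The same tests were run with an estimated correlation and with fry. Counts of called list members are given over all probe sets and adjusted over the list alone.

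The genes named were set by a rule. For each time they were, among probe sets with 1 symbol that were called and passed the fold rule, up to 12 genes with the highest and 12 with the lowest change. To these came up to 6 members with the largest test statistic of each list that was called or held at least 3 called members. CD47, HIF1A, FOS, EGR1, MYC, VEGFA and DDIT4 were named whatever their values. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined, but the square root scale was not. The plan had log2 values, with linear scores taken to log2. The square root was chosen after the scores were seen, and the filter and the fold rule were applied on it. Alternatives fixed before the data were examined were other filters, a floor, renewed quantile normalization, equal array medians, the replicate number as a block, other variance models, fold minimums of 1.5 and 3 and leaving out each array. Other scales of the deposited scores, control signals as covariates, a crossed block and a fit without the 0 h arrays were added after the data were seen.

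The procedure was tested on simulated data made for 6 h against 0 h with 4276 probe sets. It called 94% of the probe sets changed by 2 on the log2 scale in either direction, 78% of those raised by 1 and 72% of those lowered by 1, with 13 unchanged probe sets called. The simulated noise was independent between probe sets, without any shift shared across an array, so these rates may not hold for the real arrays.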

Results

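The 10 arrays followed MOLT-4 cells at 0 h, 0.5 h, 1 h, 3 h and 6 h of treatment with MABL, with 2 arrays per time. CD47, the antigen of MABL, is a membrane protein of the immunoglobulin superfamily that binds thrombospondin and SIRP alpha. The comparisons ask how expression at each time differs from 0 h, the control that the submitters chose. Changes are log2 changes from 0 h, n = 2 arrays per time, on the square roots of the deposited values read as log2, so their sizes depend on that reading. Of the called changes of genes named by the rule, 66 had a mean below log2 5 at 1 of the times compared; with a floor at that level, 27 of these were under 0.5 times as large and 55 were called. Values named as floored are those with that floor.

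CD47 mRNA was read by 4 probe sets. The brightest stood at 8.96 ± 0.025 (SD) at 0 h, 9.01 ± 0.19 at 0.5 h, 8.47 ± 0.19 at 1 h, 8.70 ± 0.077 at 3 h and 8.92 ± 0.064 at 6 h. It fell by 0.49 at 1 h (SE 0.134, adjusted p = 0.0263). That call was lost with equal array medians (-0.21, adjusted p = 0.177), after renewed quantile normalization (adjusted p = 0.0853), with no filter (adjusted p = 0.0941) and without 0 h replicate 1 (adjusted p = 0.122), 0 h replicate 2 (adjusted p = 0.0784) or 1 h replicate 2 (adjusted p = 0.153). The next brightest CD47 probe set fell by 0.90 at 1 h (SE 0.156, adjusted p = 0.00399), by 0.97 at 3 h (adjusted p = 0.00425) and by 0.80 at 6 h (adjusted p = 0.00856), from 8.59 ± 0.23 at 0 h. At 3 h and 6 h the brightest probe set differed by -0.26 and -0.04 and was not called (adjusted p = 0.183 and 0.86). The alternative settings were run for the brightest CD47 probe set only, so how the calls of the next brightest hold under them is not known. The other 2 CD47 probe sets lay below the filter on every array, with 0 h means of 4.88 and 3.01.

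Replicates correlated at 0.991 to 0.994 over the tested probe sets, and arrays of different times at 0.949 to 0.992. Signals that do not come from the cells' mRNA also moved with time. Probe sets for 18S ribosomal RNA averaged 9.03 ± 0.88 at 0 h, 10.44 ± 0.34 at 0.5 h, 10.68 ± 0.64 at 1 h, 11.20 ± 0.65 at 3 h and 11.67 ± 0.49 at 6 h. The spike-in controls, transcripts of bacterial and phage genes added in the laboratory, averaged 10.00 ± 0.29, 10.27 ± 0.28, 10.25 ± 0.19, 10.76 ± 0.034 and 10.63 ± 0.032 at these times. The difference between the 3-prime and 5-prime probe sets of ACTB, a sign of RNA quality, was 1.60 ± 0.17 at 0 h and between 1.64 and 1.75 at the later times. That of GAPDH was 0.36 ± 0.034 at 0 h and lower at each later time, between 0.22 and 0.31. The median of the tested probe sets differed from that at 0 h by -0.13 at 0.5 h, -0.29 at 1 h, -0.31 at 3 h and -0.25 at 6 h. A change relative to the array median is therefore higher than the change given by 0.13, 0.29, 0.31 or 0.25, respectively, and the values named as taken with equal array medians are relative in this way.

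After 0.5 h, DHX15, an RNA helicase of the spliceosome, fell by 2.42 (SE 0.26, adjusted p = 0.00299), from 6.50 ± 0.54 to 4.08 ± 0.012. CANX, the endoplasmic reticulum chaperone calnexin, also fell by 2.42 (SE 0.32, adjusted p = 0.00411), and SON, a splicing cofactor, fell by 2.28 (SE 0.32, adjusted p = 0.00485). Further falls were those of ST13, a cochaperone of HSP70 (-2.33), the RNA-binding protein CELF2 (-2.33), the nucleotide kinase CMPK1 (-2.30), the stress granule protein G3BP2 (-2.28), the decapping enzyme DCP2 (-2.23), DESI2 (-2.17), the replication factor subunit RFC3 (-2.16), the translation initiation factor EIF4B (-2.15) and the kinase PAK2 (-2.15). Floored, the changes of DHX15, ST13, SON, DCP2, DESI2, RFC3 and EIF4B were -1.50, -1.40, -0.85, -0.31, -0.93, -0.44 and -1.45. That of CMPK1 was -2.11. The calls of CELF2, CMPK1, G3BP2, DCP2, DESI2, RFC3, EIF4B and PAK2 were lost without 0 h replicate 1 (adjusted p = 0.0587 to 0.106), without 0.5 h replicate 2 (0.0556 to 0.0955) and with no filter (0.0574 to 0.112). That of DCP2 was lost without 0 h replicate 2 as well (0.0506). The 3 genes that rose past the fold rule were PCBP2 (1.91, SE 0.135, adjusted p = 0.00133), EIF5A (1.47) and the small nucleolar RNA gene SNORA21 (1.46; floored 0.45 and not called). Of PCBP2, which encodes an RNA-binding protein, the other 2 tested probe sets differed from 0 h by 0.01 and 0.12. EIF5A was not called without any 1 of the 4 arrays compared (adjusted p = 0.118 and 0.0563 without 0 h replicates 1 and 2, 0.0611 and 0.112 without those of 0.5 h) or with no filter (0.137), nor SNORA21 with no filter (0.0617).

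Heat shock proteins, the chaperones that fold cytosolic and mitochondrial proteins, formed the 1 list called at 0.5 h. Of its 9 measured members 6 fell and 0 rose (7 fell adjusted over the list alone), with a median change of -0.998 (camera adjusted p = 0.00074; adjusted p = 0.989 with an estimated correlation). HSPA9, the mitochondrial HSP70, fell by 1.46, HSPA4 by 1.42, the cochaperone DNAJA1 by 1.26 and HSP90AA1 by 1.14. With equal array medians 6 members fell, at a median of -0.87, and with no filter the median was -0.29. The level of 18S RNA was higher than at 0 h by 1.41 on the same arrays and that of the spike-ins by 0.27. Of 26 measured genes of DNA replication and S phase, 6 fell and 0 rose (adjusted over the list alone, also 6 and 0; camera adjusted p = 0.943), among them RRM1, a subunit of ribonucleotide reductase (-1.43), and the helicase subunit MCM6 (-1.09); with equal array medians 5 fell and 2 rose. Of 18 genes of G2 and mitosis, 4 fell and 0 rose (adjusted over the list alone 6 and 1; camera adjusted p = 0.456), including the cyclin CCNA2 (-1.41), its partner kinase CDK1 (-1.19) and the mitotic kinase AURKA (-0.998). In that list 6 fell and 1 rose with equal array medians, and the median turned from -0.099 to 0.03. The redox list had 3 falls among 13 measured genes (3 adjusted over the list alone; camera adjusted p = 0.934), with catalase, CAT, at -1.07, and with equal array medians 3 fell and 2 rose. Oxidative phosphorylation had 3 falls among 28 (2 adjusted over the list alone; camera adjusted p = 0.943), with ATP5PB at -1.08. There the balance of calls turned with the scaling, as with equal array medians 1 fell and 3 rose. The list median stayed above 0, at 0.02 as deposited and 0.15 with equal array medians. Of the genes named from these lists, HSP90AA1, DNAJA1, RRM1, MCM6, CCNA2, AURKA and CAT lost their calls without 0 h replicate 1 (adjusted p = 0.065 to 0.16), without 0.5 h replicate 2 (0.0576 to 0.225) and with no filter (0.0577 to 0.27). DNAJA1, MCM6, AURKA, CAT and RRM1 lost them without 0.5 h replicate 1 too (0.0529 to 0.0834). RRM1 lost it also without 0 h replicate 2 (0.152), without either 6 h array (0.0551) and on log2 of the deposited values (0.102).

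At 0.5 h, 728 of 4276 probe sets were called, 82 higher and 646 lower, and with equal array medians 295 higher and 656 lower. The fold rule gave 5 higher and 256 lower, and with equal array medians 12 and 186. The number called was 128 without 0 h replicate 1, 482 without 0.5 h replicate 1 and 147 without 0.5 h replicate 2, and it was 234 with the spike-in level and 9 with the 18S level as a covariate. In these fits 935 and 629 probe sets had an unadjusted p under 0.05, and the median SE was 0.174 and 0.210 in place of 0.148.

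After 1 h, ID1, an inhibitor of basic helix-loop-helix transcription factors, rose by 2.34 (SE 0.0921, adjusted p = 2.38e-05), from 5.93 ± 0.0044 to 8.27 ± 0.049. IER2, an immediate early gene, rose by 1.37 (SE 0.264, adjusted p = 0.00618). CD164, a sialomucin of blood progenitor cells, fell by 3.05 (SE 0.219, adjusted p = 0.000559), CMPK1 by 3.06 (adjusted p = 0.00128). PAK2 (-2.91) and PSMD14, a deubiquitinase of the proteasome (-2.80), fell as well. Other genes that rose were EIF5A (1.39), PCBP2 (1.34), LSM4 (1.28) and EEF1D (1.15), for the last 3 of which the other tested probe sets lay between -0.01 and 0.39. The remaining falls among the 12 lowest were those of G3BP2 (-2.61), EIF4B (-2.58), DHX15 (-2.49), AZIN1, a regulator of polyamine synthesis (-2.45), HNRNPH3 (-2.45, its other 3 probe sets at -0.49 to -0.44), SEPTIN2 (-2.44), DESI2 (-2.43) and MOB1A (-2.41). Floored, the changes of EIF4B, DHX15, SEPTIN2 and DESI2 were -1.45, -1.50, -1.18 and -0.93. The other probe sets of DESI2 and MOB1A stood at -0.76 and -0.65. EIF5A lost its call without 0 h replicate 1 (adjusted p = 0.0876), 1 h replicate 1 (0.0741) or 1 h replicate 2 (0.0561) and with no filter (0.113), as did IER2 (0.0614) and EEF1D (0.0542) with no filter.

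Heat shock proteins were lower at 1 h as well: 7 of 9 fell and 0 rose (7 adjusted over the list alone), at a median of -1.22 (camera adjusted p = 0.00264; adjusted p = 0.989 with an estimated correlation). HSPA9 fell by 1.84, DNAJA1 by 1.77 and HSPD1, the mitochondrial chaperonin, by 1.54, and with equal array medians 6 fell at a median of -0.93; with no filter the median was -0.22. Among 5 measured interferon-stimulated genes 3 rose (3 adjusted over the list alone), IFI6 by 0.74, IFITM1 by 0.64 and ISG15 by 0.44 (camera adjusted p = 0.0471; adjusted p = 0.989 with an estimated correlation). That call was also lost with equal array medians (adjusted p = 0.175), with no filter (0.407, at a median of 0.03), with the filter at log2 7 (0.126) and with the replicate block (0.0513). It was lost as well without 0 h replicate 1 (0.0622), 1 h replicate 2 (0.0683), either 3 h array (0.0523) or either 6 h array (0.0559), while fry gave 0.0238. By gene, ISG15 was not called without any 1 of the 4 arrays compared (0.119 and 0.13 without 0 h replicates 1 and 2, 0.154 and 0.0976 without those of 1 h), IFITM1 without 0 h replicate 1 (0.0826) or 1 h replicate 1 (0.0797), and IFI6 without 0 h replicate 1 (0.0705) or 1 h replicate 2 (0.104). The 18S level was higher than at 0 h by 1.65 on these arrays and the spike-in level by 0.25.

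Of 26 genes of DNA replication and S phase, 9 fell and 0 rose at 1 h (10 adjusted over the list alone, camera adjusted p = 0.456), including RRM1 (-2.27), RFC3 (-2.21) and MCM6 (-1.74). The RFC3 value is that of its brightest probe set, which changed by -1.58 at 0.5 h and is not the RFC3 probe set named at that time. With equal array medians, however, 8 rose and 6 fell and the list median turned from -0.17 to 0.11. Of 18 genes of G2 and mitosis 8 fell (9 adjusted over the list alone; camera adjusted p = 0.264), among them AURKA (-1.61) and CDK1 (-1.45). With equal array medians 7 fell and 3 rose. In the T-lineage list, 5 of 23 genes fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.934), with falls of the transcription factors MYB (-1.66), BCL11B (-1.36) and GATA3 (-1.13). With equal array medians 3 fell and 6 rose. Immediate early genes went both ways, 2 up and 1 down of 10 (2 and 1 adjusted over the list alone; camera adjusted p = 0.183), with KLF10 at -1.51 (floored -0.68); with equal array medians 6 rose and 1 fell. Of 16 genes of ribosome biogenesis 5 fell (5 adjusted over the list alone; camera adjusted p = 0.456), led by the nucleolar protein NPM1 (-1.62). With equal array medians 3 fell and 1 rose and the median turned from -0.23 to 0.06. Of 13 caspases and related genes 2 fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.911), with CASP6 at -1.49, cytochrome c, CYCS, at -1.22 and HTRA2 at 0.60. With equal array medians 2 fell and 2 rose. Of the 5 measured genes in the list of CD47 and its partners, 3 fell (3 adjusted over the list alone; camera adjusted p = 0.411), which were CD47 itself, the G protein subunit GNAI3 (-1.79) and UBQLN2 (-1.11, floored -0.70). In that list 2 fell with equal array medians. MYB and BCL11B were not called without any 1 of the 4 arrays compared: for MYB adjusted p = 0.107 and 0.0613 without 0 h replicates 1 and 2 and 0.0607 and 0.105 without those of 1 h, and for BCL11B 0.14, 0.0528, 0.067 and 0.118. CASP6 was lost without 0 h replicate 2 (0.0862) or 1 h replicate 2 (0.103), GNAI3 without 0 h replicate 1 (0.0536), and UBQLN2 without 0 h replicate 1 (0.0883), 0 h replicate 2 (0.0521) or 1 h replicate 2 (0.0774). All 5 were lost with no filter (0.0651 to 0.165).

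In all, 1213 probe sets were called at 1 h, 177 higher and 1036 lower, and with equal array medians 1389 higher and 834 lower, so that which direction held the majority depended on the scaling. The quantile normalization applied again gave 1027 higher and 870 lower. The number called was 656 without 0 h replicate 1 and 674 without 1 h replicate 2, and it was 789 with the spike-in level and 87 with the 18S level as a covariate, with 1316 and 849 at an unadjusted p under 0.05 and median SEs of 0.170 and 0.229. The fold rule gave 9 higher and 487 lower, and with equal array medians 19 and 298.

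**Figure D1:**
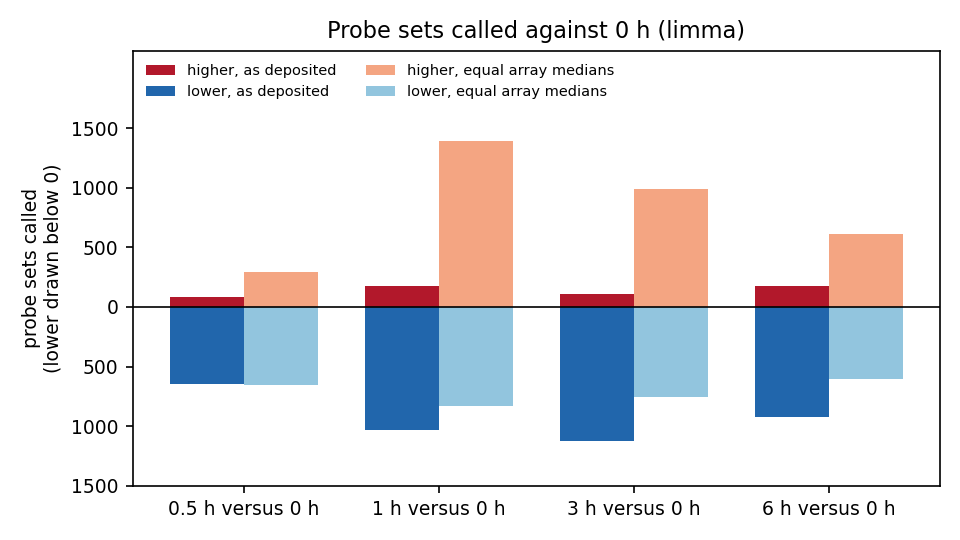
Number of called probe sets (limma, adjusted p under 0.05) higher and lower than at 0 h at each time, from the values as deposited and with equal array medians; bars start at 0. At 1 h the values as deposited gave 177 higher and 1036 lower, and equal medians gave 1389 and 834.

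After 3 h, DDIT4, a stress-induced inhibitor of mTORC1 signalling, rose by 2.67 (SE 0.143, adjusted p = 0.000266), from 6.89 ± 0.0099 to 9.56 ± 0.062. HSPA5, the main HSP70 chaperone of the endoplasmic reticulum, fell by 2.96 (SE 0.298, adjusted p = 0.00184), from 9.30 ± 0.17 to 6.35 ± 0.78. GNA15, a G protein alpha subunit of blood cells, rose by 1.60 (SE 0.154, adjusted p = 0.00184), and JUND, an AP-1 subunit, by 1.13 (adjusted p = 0.00523). TXNIP, an inhibitor of thioredoxin and glucose uptake, fell by 2.24 (SE 0.362, adjusted p = 0.00426). Other genes that rose were EEF1D (1.57), EIF5A (1.47), LSM4 (1.44), COX5B (1.30), TCF3 (1.12) and RPL14 (1.05), of which the other tested probe sets lay between 0.89 and 0.96 for EIF5A, 0.36 and 0.47 for COX5B, and -0.15 and 0.49 for the rest. Other falls were those of the DNA polymerase POLQ (-2.74), EIF5 (-2.45), the topoisomerase TOP1 (-2.42), HNRNPA3 (-2.40), the phosphatase PTPN11 (-2.37), HNRNPH3 (-2.36), PAK2 (-2.31), DHX15 (-2.26), PNMA2 (-2.21) and CELF2 (-2.18). Floored, the changes of TXNIP, POLQ, EIF5, PNMA2 and DHX15 were -0.92, -0.50, -0.34, -0.80 and -1.50. EIF5A lost its call without 0 h replicate 1 (adjusted p = 0.082) or 3 h replicate 2 (0.0609) and PAK2 without 0 h replicate 1 (0.0583). The filter also mattered for both (0.097 and 0.0657 with none) and for HNRNPA3 (0.054).

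At 3 h, 7 of 9 heat shock proteins fell and 0 rose (8 adjusted over the list alone), at a median of -1.33 (camera adjusted p = 0.00264; adjusted p = 0.989 with an estimated correlation), with HSPA4 at -1.61 and HSP90AA1 at -1.52, and with equal array medians 7 fell at a median of -1.02; with no filter the median was -0.35. Of 13 endoplasmic reticulum chaperones and unfolded protein response genes 6 fell and 0 rose (7 adjusted over the list alone; camera adjusted p = 0.25), among them HERPUD1, a factor of protein degradation from that organelle (-1.32), the disulfide isomerase PDIA3 (-1.05) and MANF (-1.04), and with equal array medians 4 fell and 1 rose. Ribosome biogenesis genes had 8 falls of 16 (9 adjusted over the list alone; camera adjusted p = 0.119), with NOLC1 at -1.49 and nucleolin, NCL, at -1.17, and with equal array medians 5 fell and 1 rose. MYC, a transcription factor that drives ribosome biogenesis, fell by 0.66 (SE 0.107, adjusted p = 0.00435). In DNA replication 11 of 26 fell (14 adjusted over the list alone; camera adjusted p = 0.183), with RFC4 at -1.26 and RRM2 at -1.13, and with equal array medians 8 fell and 4 rose. Of 6 genes of cholesterol and fatty acid synthesis 4 fell (4 adjusted over the list alone; camera adjusted p = 0.397), including the desaturase SCD (-1.12) and the squalene epoxidase SQLE (-1.07), and with equal array medians 2 fell and 1 rose. In the hypoxia list 3 of 10 rose, DDIT4, the glycolysis regulator PFKFB3 (1.07) and the peptide hormone gene ADM (0.84), and the transferrin receptor TFRC fell by 1.18 (3 and 1 adjusted over the list alone; camera adjusted p = 0.119). ADM stayed below log2 5 at 3 h, so its rise there was not called with the floor, nor without 0 h replicate 1 (adjusted p = 0.106) or with no filter (0.104). MANF and SQLE lost their calls without 0 h replicate 1 (0.0883 and 0.0624), without 3 h replicate 2 (0.0557 and 0.0535) and with no filter (0.0843 and 0.0606). On these arrays the 18S level was higher than at 0 h by 2.17 and the spike-in level by 0.76.

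At 3 h, 1236 probe sets were called, 108 higher and 1128 lower, and with equal array medians 987 higher and 760 lower. The quantile normalization applied again gave 822 higher and 798 lower, and the fold rule 13 higher and 286 lower, or 24 and 118 with equal array medians. The number called was 429 without 0 h replicate 1, 568 without 3 h replicate 2 and 646 in a fit of the 2 groups alone. In limma fits with the spike-in or the 18S level as a covariate it was 0, with 564 and 489 probe sets at an unadjusted p under 0.05 and median SEs of 0.293 and 0.272 in place of 0.148.

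After 6 h, genes known to respond to low oxygen were far higher than at 0 h. ADM rose from 2.89 ± 0.11 to 8.10 ± 0.19, by 5.21 (SE 0.20, adjusted p = 9.64e-06), which is 36.9-fold if the square roots are log2 values and 7.85-fold as a ratio of the deposited values. BHLHE40, a transcriptional repressor, rose by 3.59 (SE 0.136, adjusted p = 9.64e-06), DDIT4 by 3.40 (SE 0.143, adjusted p = 9.67e-06) and BNIP3, a mitophagy receptor, by 3.02 (SE 0.212, adjusted p = 0.000288). ADM and BHLHE40 started below log2 5, and floored they rose by 3.10 and 1.27. P4HA1, a collagen prolyl hydroxylase subunit, rose by 2.53 (floored 1.27; adjusted p = 0.0014), and HILPDA, a lipid droplet protein, by 2.08 (adjusted p = 0.000498). Of the 10 measured members of the hypoxia list 9 rose and 0 fell (9 adjusted over the list alone), at a median of 2.24, with equal array medians of 2.49, floored of 1.33 and with no filter of 0.15 (camera adjusted p = 4.66e-13; adjusted p = 0.344 with an estimated correlation). The list has 31 genes on the array, and ADM, BHLHE40 and P4HA1 were among those that passed the filter through their 6 h arrays. The remaining measured member, TFRC, differed by -0.04. HIF1A, the oxygen-regulated transcription factor subunit, and VEGFA lay below the filter on every array; HIF1A averaged 3.40 ± 0.042 at 0 h and 3.54 ± 0.29 at 6 h, and the VEGFA probe set with the highest 6 h level 2.86 ± 0.0048 and 3.81 ± 0.48.

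Genes of glucose use were also higher at 6 h. Of 19 genes of glycolysis and glucose transport 8 rose and 2 fell (11 and 2 adjusted over the list alone), at a median of 0.41 (camera adjusted p = 2.87e-07; adjusted p = 0.989 with an estimated correlation). The glucose transporters SLC2A3 (1.68) and SLC2A1 (1.18), the hexokinases HK2 (1.19) and HK1 (0.97) and the aldolase ALDOC (1.05) rose, and with equal array medians 15 rose and 0 fell, at a median of 0.66. Floored, SLC2A3 rose by 0.57, and SLC2A1, at 0.53, was not called. Without 0 h replicate 1 and with no filter, SLC2A1 (adjusted p = 0.0523 and 0.0571) and KLF10 (0.0565 and 0.0592) lost their calls. KLF10 did so on log2 of the deposited values too (0.0597). Of 10 immediate early genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.00532; adjusted p = 0.989 with an estimated correlation), with IER3 at 2.06 (floored 0.56), JUND at 1.59 and KLF10 at 1.17; with equal array medians 6 rose and 1 fell. The call of this list was also lost with the filter at log2 7 (adjusted p = 0.111, at a median of 0.14) and with fry (0.0552). With no filter it was kept (adjusted p = 0.000608), but at a median of 0.02. FOS lay below the filter at 2.31 at 0 h and 2.31 at 6 h, and the brighter EGR1 probe set, also below it, at 2.35 ± 0.014 and 4.24 ± 0.15.

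MYC went the other way, from 10.38 ± 0.080 at 0 h to 9.05 ± 0.073 at 6 h, a fall by 1.33 (SE 0.107, adjusted p = 0.000498). Its level also followed the 18S signal inversely, with a correlation of -0.806 over the arrays and -0.9075 once the mean of each time was subtracted. The latter rests only on the replicate differences at the 5 times. Of 16 genes of ribosome biogenesis and MYC targets 8 fell and 0 rose (9 adjusted over the list alone), at a median of -0.53 (camera adjusted p = 0.0169; adjusted p = 0.989 with an estimated correlation), and with equal array medians 6 fell at a median of -0.28. That call was also lost with the filter at log2 7 (adjusted p = 0.0874) and without 6 h replicate 2 (0.0559). Examples were NIP7 (-1.66), ODC1, the first enzyme of polyamine synthesis (-1.46), and NOP16 (-1.15). Endoplasmic reticulum chaperones had 8 falls of 13 (8 adjusted over the list alone; camera adjusted p = 0.0748), with HSPA5 at -1.39 and MANF at -1.16, and heat shock proteins 5 falls of 9 (5 adjusted over the list alone; camera adjusted p = 0.0612), with HSPA9 at -1.16. In DNA replication 11 of 26 fell (12 adjusted over the list alone; camera adjusted p = 0.233), led by RRM2, the other subunit of ribonucleotide reductase (-1.86), and CDC25A, a phosphatase that activates cyclin-dependent kinases (-1.22), and with equal array medians 7 fell and 3 rose. TXNRD1, thioredoxin reductase, fell by 1.65 and was 1 of 3 falls among 13 redox genes (3 adjusted over the list alone; camera adjusted p = 0.746). Their median turned from -0.23 to 0.01 with equal array medians. In the BCL2 family 2 of 8 fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.943), with PMAIP1, a promoter of apoptosis, at -1.26, MCL1, an inhibitor of it, at -0.73 and BIK at 0.78. The median turned from -0.02 to 0.23 with equal array medians. HSPA5, MANF and MCL1 lost their calls without 0 h replicate 1 (adjusted p = 0.0858, 0.0666 and 0.0675), without 6 h replicate 1 (0.0678, 0.0568 and 0.0519) and with no filter (0.0996, 0.0646 and 0.0576). HSPA5 was not called on log2 of the deposited values (0.053). On these arrays the 18S level was higher than at 0 h by 2.64 and the spike-in level by 0.63.

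Other genes that rose at 6 h were EFNA4, an ephrin ligand (2.49; floored 0.43 and not called), CCNG1, cyclin G1, a p53 target (2.44; floored 1.90), BEND5 (1.99; floored 0.86) and GNA15 (1.97). With the mean of each time subtracted, levels of some named genes followed the 18S signal inversely, such as MCM6 (correlation -0.987) and DHX15 (-0.8765). Others did not, such as DDIT4 (0.0511) and ID1 (-0.0667). Several genes that rose at 6 h correlated with the 18S signal over the arrays, such as JUND (0.823), SLC2A3 (0.754), GNA15 (0.753), EFNA4 (0.738) and ADM (0.577). With the mean of each time subtracted these correlations were 0.591, 0.512, 0.0622, 0.694 and -0.413. FOLR1, a folate receptor, also rose at 6 h (2.28, SE 0.63, adjusted p = 0.0309), but its levels followed the 18S signal more closely. Its correlation was 0.963 over the arrays and 0.976 once the mean of each time was subtracted. Its call was lost with no filter (adjusted p = 0.227) and without 0 h replicate 1 (0.197), 6 h replicate 1 (0.166) or 6 h replicate 2 (0.0549). The lowest changes were those of SEH1L, a nucleoporin (-2.65), SAR1A, a GTPase of vesicle transport (-2.39, its other probe set at -0.37), NETO2 (-2.13), SRSF6, a splicing factor (-2.10), GCH1 (-2.09), EIF5 (-2.07), the calcium pump ATP2A2 (-1.98), MTMR4 (-1.98), the zinc transporter SLC39A14 (-1.91), RAN (-1.90, its other probe set at -0.54) and TSN (-1.86, its other at -0.52). Floored, EIF5 fell by 0.34, MTMR4 by 1.01 and SLC39A14 by 1.09, and NETO2, at -0.089, was not called. TSN lost its call without 0 h replicate 1 (adjusted p = 0.0864) or 2 (0.0654) and SLC39A14 without 0 h replicate 1 (0.0663). Both (0.133 and 0.0904) and GCH1 (0.0725) were not called with no filter. At 6 h, 1099 probe sets were called, 174 higher and 925 lower, and with equal array medians 613 higher and 603 lower; the fold rule gave 40 higher and 175 lower, but 60 and 67 with equal array medians and 56 and 79 after renewed quantile normalization. The number called was 426 without 0 h replicate 1 and 534 without 6 h replicate 1, and it was 21 with the spike-in level and 6 with the 18S level as a covariate, with 717 and 429 at an unadjusted p under 0.05 and median SEs of 0.257 and 0.315.

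Successive times were compared to place these changes. From 0.5 h to 1 h limma called 2 probe sets, those of ID1 (2.25, SE 0.0921, adjusted p = 3.21e-05) and of the sodium pump subunit ATP1B3 (-0.89, SE 0.101, adjusted p = 0.0453), both named after their values were seen; 554 had an unadjusted p under 0.05. Leaving out any 1 array other than 1 h replicate 1 left 1 higher and 0 lower, so ATP1B3 was called in none of those 9 fits. From 1 h to 3 h, DDIT4 rose by 3.10 (SE 0.143, adjusted p = 4.07e-05), and ID1 fell by 2.25, TXNIP by 2.23 (floored -0.91), HSPA5 by 1.88 and HERPUD1 by 1.73. In that comparison 161 probe sets were called, 83 higher and 78 lower, with equal array medians 223 higher and 178 lower. The count was 80 without either 0 h array, 76 without either 0.5 h array, 24 without 1 h replicate 1, 12 without 1 h replicate 2 and 40 without 3 h replicate 1.

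From 3 h to 6 h, ADM rose by 4.37 (SE 0.20, adjusted p = 2.61e-05), BHLHE40 by 3.53 (SE 0.136, adjusted p = 1.65e-05), P4HA1 by 3.12 and BNIP3 by 3.03 (floored 3.10, 1.27, 1.27 and 2.70), and 9 of the 10 measured hypoxia genes were called higher. CCNG1 rose by 2.90 (floored 1.90), and MYC fell by 0.67 (adjusted p = 0.0101). Here 303 probe sets were called, 214 higher and 89 lower (equal array medians: 325 and 201). The count was 142 without 3 h replicate 2 and 143 without 6 h replicate 2.

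Over all times the F test called 1694 of 4276 probe sets (39.6%), of 1196 genes, and 995 without 0 h replicate 1. The submitters' fold rule at any time was passed by 695 probe sets, 48 upward and 653 downward with some in both, and with equal array medians by 80 upward and 384 downward. On log2 of the deposited values, the other reading of their scale, 73 probe sets passed it.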

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

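The tests of the early fall, and for the hypoxia genes those of the 0 h arrays and of time in culture, were chosen only after the result was seen. The splits of the arrays were set before. For the 18S test of the hypoxia genes, only its prediction was written before its result was seen. The control signals as covariates were themselves added after the data were seen.

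Some named genes were called lower at an early time and higher at a later one, and the change between these times was itself called by limma. As the genes were chosen for opposite calls on the same arrays, that further call adds no separate support. DDIT4 fell by 1.33 at 0.5 h and rose by 2.67 at 3 h and 3.40 at 6 h, differences of 4.00 (SE 0.143, adjusted p = 1.08e-05) and 4.73 (adjusted p = 2.79e-06). KLF10, a transcriptional repressor induced by TGF-beta, stood 3.14 higher at 6 h than at 0.5 h (SE 0.22, adjusted p = 0.000157) and 2.68 higher than at 1 h (adjusted p = 0.000253), after falls by 1.97 and 1.51 from 0 h, each of them -0.68 with a floor at log2 5, where the differences were 1.85. BNIP3 was 4.53 higher at 6 h than at 1 h (SE 0.212, adjusted p = 1.57e-05), and CCNG1 3.53 higher (SE 0.261, adjusted p = 0.000163), but with that floor these differences were 2.70 and 1.90 and neither gene differed at 1 h from 0 h, so their falls rest on levels below the filter. PFKFB3 was 1.49 higher at 3 h than at 1 h (SE 0.121, adjusted p = 0.00245) and 2.36 higher at 6 h than at 1 h (adjusted p = 2.77e-05), and its fall at 1 h was not called with equal array medians (adjusted p = 0.403), with no filter (0.0934) or without 0 h replicate 1 (0.171), 0 h replicate 2 (0.0728), either 0.5 h array (0.0539) or 1 h replicate 2 (0.187). INSIG1, a regulator of cholesterol synthesis, was 0.95 higher at 6 h than at 3 h (SE 0.110, adjusted p = 0.00327), and its fall at 3 h was not called with equal array medians (adjusted p = 0.297) or without 0 h replicate 1 (0.0834) or 3 h replicate 2 (0.0633).

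Control probe sets outside the tests were brighter on average on the later arrays than at 0 h. At 6 h the 18S ribosomal RNA probe sets were higher than at 0 h by 2.64 and those of 28S by 2.15, and all 8 later arrays lay above both 0 h arrays for each. The hybridisation spike-ins were higher by 0.63 at 6 h, with 6 of 8 later arrays above both 0 h arrays.

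A set of 246 probe sets was chosen for being called lower and passing the fold rule at 0.5 h; as that choice enlarges its own change from 0 h, sets chosen against 1 of the 0 h arrays were measured against the other, a single array, with intervals from the spread at the later times, and lay lower at 1 h, relative to the other tested probe sets, by 1.36 (95% interval of the change -2.08 to -0.64) and 1.62 (-2.43 to -0.81). From 1 h to 6 h the 246 rose by 1.26 relative to the others (0.83 to 1.68), although both 6 h arrays had higher spike-in levels than both 1 h arrays. On these arrays this argues against a brighter signal as the whole cause. The spike-in difference was only 0.38, however, with an interval that includes 0 (-0.13 to 0.90). With that level as a covariate the rise was 1.34 (0.70 to 1.99), or 1.04 (-0.96 to 3.03) on the 1, 3 and 6 h arrays alone. Against the other 0 h array the changes at 1 h with this covariate were -1.39 (-2.54 to -0.24) and -1.92 (-4.58 to 0.74). How much of the fall follows the spike-in level therefore stays open. The 18S signal as the whole cause is argued against in the same way and for these arrays only. Both 6 h arrays lay above both 1 h arrays, but the difference was 0.98 with an interval that includes 0 (-0.63 to 2.59). With the 18S level as a covariate the rise was 1.45 (1.06 to 1.85), or 1.47 (0.50 to 2.43) on the 1, 3 and 6 h arrays alone. How much of the fall follows the 18S level stays open too, at -1.13 (-2.20 to -0.065) and -1.08 (-3.07 to 0.92) against the other 0 h array. Loss of 5-prime sequence through RNA degradation cannot be told apart, as from 0 h to 1 h the 3-prime to 5-prime difference of ACTB changed by 0.0456 (-0.30 to 0.39) and that of GAPDH by -0.14 (-0.32 to 0.051). A response of the cells to the antibody, GAM, the wash or the handling stays open and untested, and so does probe base composition, because no probe sequence was analysed here.

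The hypoxia genes at 6 h form the other pattern, a mean rise of 2.35 over the 10 measured members (SE 0.13), whose median of 2.24 was 1.33 with the floor, against a list median of 0.15 with no filter. Unusual 0 h arrays are argued against as the whole cause, since 9 of the 10 were also called higher at 6 h than at 3 h. That count was partly fixed by the filter, which ADM, BHLHE40 and P4HA1 passed through their 6 h arrays. BNIP3, at 4.68 at 0 h, may have done so too, so for these genes the count decides nothing. DDIT4, at log2 5 or higher on all 10 arrays, rose by 0.73 from 3 h to 6 h (limma adjusted p = 0.0228). With the 18S level as a covariate the mean rise was 2.55 (1.72 to 3.38), which argues against that signal as the whole cause for the measured members. Part of this rise was also fixed by the filter, as the mean includes ADM, BHLHE40 and P4HA1. The covariate was fitted on differences between replicates, while the 18S level differed by 2.64 between 0 h and 6 h. The size of its share therefore stays open. Time in culture or handling without the antibody cannot be told apart from the antibody or GAM, because 0 arrays of untreated cells at 6 h were among the samples. Crowded or settled cells may lack oxygen without any antibody.

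The number of called probe sets was set against other splits of the 10 arrays into 5 pairs, 100 of 945 including the real one. The F test called 1694 by time and at most 929 in another drawn split, so 1 of 100 splits gave as many, which argues against chance pairing of the arrays. The fold rule at any time gave 695 by time and at most 652 in another drawn split, again 1 of 100. With so narrow a margin, and most splits not drawn, this count does not exclude chance. Every split also kept 0 h replicate 1 in the reference pair of the fold rule.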

How the results depend on the processing

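The settings chosen only after the data were seen were the square root scale itself, log2 of the deposited values, the spike-in and 18S levels as covariates, the crossed block, the fit without the 0 h arrays and equal array medians for the list tests.

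Of 299 alternative values of 14 counts, 194 lay within 1.5 times and 105 beyond. Among the 275 called gene and time pairs named, 0 changed direction under the settings run for single genes, which were no filter, the floor, both scalings, leaving out each array, the replicate block and log2 of the deposited values. No filter, the block and leaving out an array of another time cannot change a direction. A floored change of 0 was counted as not reversed, so this result carries little weight. Covariates, the log2 7 filter, the crossed block and other variance models were not run for single genes. Of the 275, 237 were called with equal array medians, 246 on log2 of the deposited values, 158 with no filter and 156 without 0 h replicate 1. Signal over background limits genes below log2 5, whose changes depend on the lower end of the scale. Where nothing else is said, the cause was not tested.

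With no filter, which tests more probe sets, the calls were 307 at 0.5 h, 680 at 3 h, 676 at 6 h, 5 from 0.5 h to 1 h, 21 from 1 h to 3 h, 114 from 3 h to 6 h, 834 by the F test and 24 list tests. With the filter at log2 7, which tests fewer, they were 475 at 0.5 h, 767 at 1 h, 10 from 0.5 h to 1 h and 279 from 1 h to 3 h, and the fold rule gave 128, 267, 133 and 106 at 0.5, 1, 3 and 6 h and 373 at any time. Quantile normalization again gave 1897 at 1 h, 328 from 1 h to 3 h, 524 from 3 h to 6 h and 155 and 135 by the fold rule at 3 h and 6 h. Equal array medians gave 2223 at 1 h, 401 from 1 h to 3 h and 526 from 3 h to 6 h, and by the fold rule 317, 142 and 127 at 1, 3 and 6 h and 458 at any time.

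On log2 of the deposited values, 1 probe set was called from 0.5 h to 1 h and 77 from 1 h to 3 h, and the fold rule gave 21, 53, 19 and 16 at the 4 times and 73 at any time. The spike-in covariate gave 234, 789, 0 and 21 at 0.5, 1, 3 and 6 h, 1 from 0.5 h to 1 h, 5 from 1 h to 3 h, 159 from 3 h to 6 h and 763 by the F test. The 18S covariate gave 9, 87, 0 and 6, then 1 from 0.5 h to 1 h and 785 by the F test. The 18S level rises at each successive time, and the spike-in level is higher at 3 h and 6 h than at the earlier times. In these limma fits the median SE at 3 h went from 0.148 to 0.293 with the spike-in level and 0.272 with the 18S level. At 3 h, 564 and 489 probe sets had an unadjusted p under 0.05.

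Whether the replicate numbers shared across times pair the arrays stays open: the differences between replicates correlated at 0.0392 to 0.147 among 0, 0.5, 1 and 3 h, and at -0.231 to -0.0447 between these and 6 h, where the numbers may be exchanged. With the number as a replicate block, 738, 1197, 1247 and 1137 probe sets were called at 0.5, 1, 3 and 6 h, 1 from 0.5 h to 1 h, and 7 list tests, without that of the interferon genes at 1 h. Numbers crossed at 6 h gave 26, 385 and 488 for the successive times.

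A fit without the 0 h arrays gave 1 from 0.5 h to 1 h and 80 from 1 h to 3 h. Fits of the 2 groups alone gave 646 at 3 h and 1, 2 and 8 for the successive times, with fewer samples for the spread. A fold minimum of 1.5 gave 639, 919, 858 and 745 and 1433 at any time, and one of 3 gave 41, 142, 44 and 35 and 183. Against each 0 h array the fold rule gave 196 at 3 h and 141 at 6 h. Of the 8 called list tests, camera with an estimated correlation kept 0, with 0 of 108 tests called and 2 at an unadjusted p under 0.05, against 22 at that p with the preset correlation, and fry called 28.

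Leaving out each array in turn, where the lone array of a time is assumed to vary like the others, gave 128 to 792 calls at 0.5 h, 656 to 1203 at 1 h, 429 to 1187 at 3 h, 426 to 1187 at 6 h, 1 to 2 from 0.5 h to 1 h, 12 to 130 from 1 h to 3 h, 142 to 369 from 3 h to 6 h and 995 to 1713 by the F test. The lowest counts against 0 h and by the F test were those without 0 h replicate 1, the lowest from 1 h to 3 h that without 1 h replicate 2 and the lowest from 3 h to 6 h that without 3 h replicate 2. The fold rule gave 215 to 437, 444 to 658, 236 to 664 and 173 to 451 at the 4 times and 630 to 857 at any time, and 6 to 10 list tests were called.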

Other observations

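Further genes with large changes between successive times were picked only after their values were seen, and no explanation was tested for them. NRN1, neuritin, rose by 2.37 from 3 h to 6 h (SE 0.117, adjusted p = 3.58e-05), JAM3, a junctional adhesion molecule, by 2.21 (SE 0.177, adjusted p = 0.00065), and ANXA1, annexin A1, by 2.09 (SE 0.331, adjusted p = 0.00978). BNIP3L, a mitophagy receptor related to BNIP3, rose by 3.19 at its most changed probe set (1.91 with a floor at log2 5; SE 0.178, adjusted p = 7.64e-05). Over the same interval SRPRB, a subunit of the signal recognition particle receptor, fell by 1.55 (adjusted p = 0.0149), YRDC, which acts in tRNA modification, by 1.36 (adjusted p = 0.00609), AKAP1, a mitochondrial anchoring protein, by 1.25 (adjusted p = 0.00736) and CIRBP, a cold-inducible RNA-binding protein, by 1.18 (adjusted p = 0.00327). From 1 h to 3 h, PMAIP1 fell by 1.38 (SE 0.123, adjusted p = 0.00312).

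In the amino acid response list 4 of 18 measured genes fell at 6 h and 0 rose (4 adjusted over the list alone; camera adjusted p = 0.911), among them MTHFD2, a mitochondrial folate enzyme (-1.10; adjusted p = 0.0754 without 0 h replicate 1 and 0.0738 with no filter), and the arginine transporter SLC7A1 (-0.82); with equal array medians 3 fell and 3 rose. In the p53 target list 1 of 7 rose, CCNG1, and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.995), TRIAP1 (-0.93) and RPS27L (-0.51, not called with equal array medians, with no filter, on log2 of the deposited values or without 0 h replicate 1 or 6 h replicate 2, at adjusted p = 0.213, 0.0938, 0.0518, 0.15 and 0.119); its median was -0.18, its mean 0.09 and its median with equal array medians 0.06. Markers of other cell types were nearly unmeasured: 1 of the myeloid list, 1 of the B-cell list, 0 of the cytotoxic list and 1 of the erythroid, stromal and epithelial list passed the filter.

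Of the genes with a probe set among the 246 that fell early, 77 further tested probe sets had a median change of -0.65 at 0.5 h. Of these, 72.7% lay below -0.5, against 13.6% of the tested probe sets with 1 symbol that belong to other genes. Both shares were read on the same 0 h and 0.5 h arrays that chose the 246, so they add no separate support.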
